A study of Oryza sativa with 12 samples.

How the data were processed

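RNA from leaves of wild type IAPAR9 and idr1-1 rice was sequenced in 12 libraries, 3 biological replicates for each of 4 groups: wild type control, wild type drought, idr1-1 control and idr1-1 drought. Groups, tissue and replicate numbers were taken from the labels, whose extraction protocol speaks of seedlings where the tissue label says leaf. The deposited values are estimated counts, not scaled to depth, in 1 file per library with 55986 entries, of which 55801 carry LOC_Os locus identifiers and 185 are other gene predictions. HISAT2 2.1.0 and featureCounts 1.6.3 were used, per the submitters' processing notes; the genome build, the annotation release, strandedness and counting options are not given in the sources used here. Of the nonzero values 13.8% were not whole, which shows that some reads were shared in fractions, and near-identical copies, overlapping genes and antisense pairs are therefore uncertain. Values were rounded to whole numbers, which changed a library total by at most 0.0011%.

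Total counts were 19100444 to 25109848 per library, and the 20 most abundant genes took 12.3% to 16.9% of them. A floor of 3 counts corresponds to 0.119 to 0.157 CPM in a single library. Where a group held 0 counts, a fold was computed against 3 counts summed over the group and is given as "at least". With 1 to 3 counts the ratio is given with an exact (Clopper-Pearson) 95% counting interval. Intervals and floors cover counting error only, since molecular identifiers are not given in the sources used here. No pair of replicates was a duplicate, the chi-square per gene over genes with at least 20 counts in the pair being 8.20 or more.

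Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr left 22833 genes, TMM factors were computed, and edgeR's quasi-likelihood test was fitted over all 12 libraries with 1 mean per group (8 residual degrees of freedom, biological coefficient of variation 0.17). Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. The 5 contrasts were drought against control in each genotype, idr1-1 against wild type in each treatment, and the difference of the drought responses. Fold changes are log2, with a standard error from the fold change and its F statistic. Correlations of the responses are descriptive.

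The same steps were tested on simulated counts drawn from the real means and library sizes with 200 genes changed. Of 22833 genes simulated, 22456 passed the filter for drought against control in wild type. There 55% of 2-fold and 85% of 4-fold changes were recovered and 2.8% of calls were false. For the same contrast in idr1-1 (22468 genes) the values were 65%, 89% and 4.3%. For the genotypes they were 62%, 83% and 2.7% in control (22475 genes) and 65%, 87% and 4.4% in drought (22468 genes), and for the difference of responses 37%, 76% and 6.6% (22468 genes). Directions were right in 100% of recovered genes. The simulation changed only 200 genes and held no library unlike its replicates, so these rates need not hold for the real comparisons.

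Gene names need a caution. The files do not pair locus identifiers with names, and 0 of their LOC_Os identifiers were found in the gene table used here (assembly ASM3414082v1). The plan was to use a locus only where the files or that table paired it with its name, and this could not be done. The names come from published locus assignments recalled for 234 members of 26 lists, fixed before the data were examined. A member was used only where the table held its name on the chromosome its locus identifier gives and in the same order among the list members. Of 233 members in the files, the table held 164 names, 2 of them only on another chromosome, and 162 were used, while 70 were not named by the table. This check departs from the plan and would not detect a name assigned to a neighbouring locus, so each name is an assignment and the locus identifier is what was measured. Some table names differ from the planned ones, such as RAB21 for RAB16A and PCL1 for LUX. Lists by protein family were dropped because no product descriptions were held. The wax list had 0 usable members and is not analysed here. GS3 is not analysed here.

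The lists covered G protein subunits, LEA proteins and dehydrins, abscisic acid metabolism, clade A phosphatases 2C, stress transcription factors, compatible solutes, reactive oxygen removal, NADPH oxidases, photosystems, carbon fixation, chlorophyll synthesis and breakdown, aquaporins, gibberellin, brassinosteroid, jasmonate, defence, phytoalexins, heat shock, the clock, wax, and markers of cell division, secondary walls, shoot apex, inflorescence and root. Photosystems kept 3 of 23 planned members. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and fry as alternatives. With an estimated correlation the calls that held were the LEA proteins and heat shock genes in both drought responses. For the 3 secondary-wall genes the estimate was 0.96 to 0.97. It was also above 0.01 in other lists called at the preset: LEA proteins (0.37 to 0.47), phosphatases 2C (0.38 to 0.45), aquaporins (0.35 to 0.38) and the clock in the idr1-1 response (0.66). For heat shock genes it was -0.04 to -0.01, and for phytoalexins in the idr1-1 response 0.02. At the preset correlation the members of the lists with high estimates count as nearly independent, so their camera p values at this setting are too low. Counts of members are given over all genes tested and adjusted over the list alone.

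Named genes follow a rule set before the data were examined: RGA1 and the other G protein subunits, up to 4 members with the smallest adjusted p from each list with a member past the threshold, and otherwise the most abundant member. A further part, the largest changes among named genes, could not be applied, so at most 2 loci that rose and 2 that fell are given per comparison by identifier. Members outside this rule are named where the text gives a list's counts adjusted over the list alone, and PIP2-7 and HSFA2D as the members that fell in wild type, and the whole secondary wall list is named wherever it is described; these were chosen after their values were seen.

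The alternatives planned were DESeq2 size factors, library size alone, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, fits of 2 groups only and leaving out each replicate. Sample quality weights in limma-voom, a robust fit, lists with all fixed members and a fit without replicate 3 of drought-stressed idr1-1 were added after seeing the data. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.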

Results

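The series measured messenger RNA by sequencing in leaves of rice (Oryza sativa). The wild type was IAPAR9, an upland cultivar, and the mutant was idr1-1, which is in the same background. The study is known to place the idr1-1 lesion in RGA1, the alpha subunit of the heterotrimeric G protein, a membrane switch that relays hormone and stress signals. Plants 5 weeks old grew in concrete tanks and were either kept without stress or left to dry until soil moisture reached 10%. Each of the 4 combinations of genotype and treatment had 3 biological replicates, which made 12 libraries. Total counts ran from 19100444 to 25109848 per library, and between 28871 and 30190 genes had a count in each. The files hold locus identifiers alone, and each gene name stands for the locus assigned to it. Levels are given as normalised CPM (counts scaled to a common library size), mean ± SD over 3 replicates.

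Drought and control leaves separated along the component that held 63.0% of the variance, and the control libraries of the 2 genotypes separated along the next, which held 12%. Replicates within a group correlated at 0.983 to 0.988 (Pearson r of log2 CPM across genes) except in drought-stressed idr1-1, where the values were 0.951 to 0.979. There, replicate 3 stood apart from replicates 1 and 2. It correlated at 0.970, 0.968 and 0.961 with the wild type drought libraries and at 0.966 and 0.951 with replicates 1 and 2 of its own group. Its difference per gene from them (chi-square 85.6 and 88.9 against at most 21.4 for the other pairs) was the highest among replicates.

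**Figure D1:**
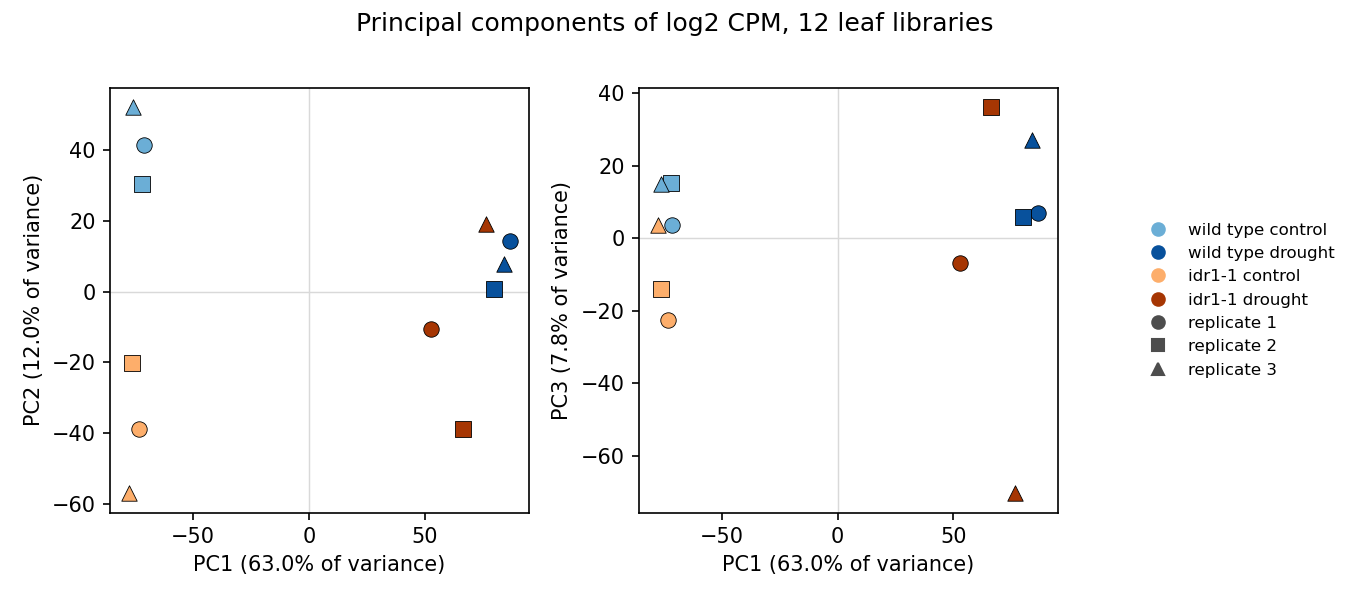
Principal components of log2 CPM for the 12 leaf libraries, with the share of the variance on each axis; colours give the group and shapes the replicate. Control and drought libraries separate along the first axis (63.0% of the variance), and replicate 3 of drought-stressed idr1-1 lies far from its group on the third (7.8%).

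RGA1 (LOC_Os05g26890) was lower in idr1-1 in both treatments. Its level was 28.6 ± 3.10 CPM in wild type control leaves and 11.9 ± 0.699 in idr1-1 control leaves (log2 fold change -1.27, SE 0.11, adjusted p = 5e-04). Under drought the levels were 25.3 ± 1.49 and 12.5 ± 1.55 CPM (-1.02, SE 0.11, adjusted p = 0.0053). Every idr1-1 library, at 11.1 to 14.1 CPM, lay below the lowest wild type library, at 23.9 CPM. RGB1, the beta subunit, gave log2 fold changes of 0.05 (adjusted p = 0.77) and 0.00 (adjusted p = 0.99) between genotypes in control and drought. RGG1, a gamma subunit, had 4 to 12 counts summed over a group and was too low to test. The drought call for RGA1 was lost when only the 2 drought groups entered the fit (adjusted p = 0.12).

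The first comparison asks how wild type leaves responded to drought. Of 8 tested late embryogenesis abundant (LEA) proteins and dehydrins, which protect cells from water loss, 7 rose and 0 fell. RAB21 (LOC_Os11g26790), a dehydrin, went from 1 count over the 3 control libraries to 884 ± 142 CPM, a ratio of 56100 (95% counting interval 10100 to 2220000), and LEA3-1 (LOC_Os05g46480) reached 192 ± 46.5 CPM from 2 counts (ratio 6080, 1680 to 50200). The control counts of both lay in wild type control replicate 2 alone. Without it the log2 fold changes went from 15.38 to 17.22 for RAB21 and from 12.39 to 15.02 for LEA3-1. RAB16B rose by 10.70 (log2, SE 0.31) and RAB16C by 3.53 (SE 0.21). Of 9 clade A protein phosphatases 2C, which hold abscisic acid signalling down, 7 rose and 0 fell, among them PP2C68 (4.28, SE 0.30, adjusted p = 1.1e-06) and PP2C49 (4.68, SE 0.37, adjusted p = 2.7e-06). Of 5 genes of abscisic acid synthesis and breakdown, 3 rose: NCED3 (LOC_Os03g44380), a dioxygenase that commits carotenoids to abscisic acid, by 3.79 (SE 0.31, adjusted p = 3.3e-06), and the hydroxylases ABA8OX1 by 1.49 and ABA8OX2 by 0.61, which break the hormone down. Adjusted over the list alone, the counts were 7 up and 0 down, 8 up and 0 down, and 3 up and 0 down. Both larger groups passed camera with the preset correlation (adjusted p = 3.1e-20 for LEA proteins and 3.8e-08 for the phosphatases) and the abscisic acid metabolism list did not (adjusted p = 0.14). The phosphatases gave adjusted p = 0.11 with an estimated correlation, and the LEA proteins 0.014.

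Water channels and heat shock proteins also rose in wild type. Of 13 aquaporins, 9 rose and 1 fell (10 and 2 adjusted over the list alone; camera adjusted p = 5.9e-06, and adjusted p = 0.2 with an estimated correlation). PIP1-2 went from 314 ± 19.2 to 943 ± 47.4 CPM (log2 1.59, SE 0.11) and PIP2-6 rose by 2.18 (SE 0.18), while PIP2-7, the most abundant member in control leaves at 3010 ± 234 CPM, fell to 1530 ± 25.3. Of 9 heat shock genes, 5 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 5.9e-06, and adjusted p = 0.014 with an estimated correlation). HSP101, a disaggregase, rose by 2.59 (SE 0.12), the small heat shock protein HSP17.7 by 3.95 (SE 0.28), and the heat stress factor HSFA2D had a log2 fold change of -1.52 (SE 0.41). Of 4 genes for compatible solutes, 2 rose and 1 fell: P5CS1 and P5CS2, of proline synthesis, rose by 3.20 (SE 0.14) and 2.08 (SE 0.35), and TPP1, a trehalose-phosphate phosphatase, had -3.61 (SE 0.47). Among 9 stress transcription factors 3 rose and 1 fell, led by BZIP23 (2.37, SE 0.13) with DREB1C at 4.18 (SE 0.71; 5.29 without wild type control replicate 1 and 3.52 without wild type drought replicate 1). The solute and transcription factor lists had the same counts adjusted over the list alone and camera adjusted p = 0.075 and 0.09. Over the 6 solute genes as fixed, 2 rose and 3 fell (median log2 fold change -0.29, camera adjusted p = 0.93). Over all 16 tested members of the transcription factor list as fixed, whether or not the gene table bears the name out, 9 rose and 1 fell (camera adjusted p = 4.3e-05, and adjusted p = 0.19 with an estimated correlation).

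The phytoalexin, defence and clock lists did not pass camera in wild type. Of 8 genes for diterpenoid phytoalexins, the antimicrobial compounds of rice, 5 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 0.087). CYP99A2, CPS4 and KSL4 of momilactone synthesis had log2 fold changes of -4.89 (SE 0.65), -3.14 (SE 0.50) and -3.11 (SE 0.84), the last being -4.62 without wild type drought replicate 1. Among 4 defence regulators and pathogenesis-related genes, WRKY62 (-4.15, SE 0.95) and WRKY76 (-2.27, SE 0.72) fell, and 4 did adjusted over the list alone (camera adjusted p = 0.21). Over the 7 defence genes as fixed, 2 rose and 3 fell (2 and 5 adjusted over the list alone, camera adjusted p = 0.46). Of 8 clock genes, 4 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.075): PCL1 went from 241 ± 87.9 to 8.86 ± 3.64 CPM, PRR95 had -1.02 (SE 0.15) and PRR1 -0.95 (SE 0.10), and LHY rose by 2.35 (SE 0.24). Over the 9 clock genes as fixed, 5 fell and 1 rose (camera adjusted p = 0.04, and adjusted p = 0.78 with an estimated correlation). The clock list was fixed as a check of the hour of harvest. Whether control and drought plants were harvested at the same hour was not tested. Any such difference would be part of the calls between drought and control in both genotypes and cannot be told apart from drought here.

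Genes of chloroplasts and of reactive oxygen removal moved both ways in wild type. Of 14 catalases, ascorbate peroxidases and superoxide dismutases, 7 rose and 3 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.36). The chloroplast superoxide dismutase SODCP rose by 0.99 (SE 0.13), while the catalase CATA fell by 1.54 (SE 0.26) and APX7, a chloroplast ascorbate peroxidase, by 1.01 (SE 0.12). The NADPH oxidase RBOHB fell by 0.72 (SE 0.13). Of 9 genes of chlorophyll synthesis 2 rose (1 adjusted over the list alone), CAO by 0.84 (SE 0.18) and GluTR by 0.99 (SE 0.34), and of 4 for its breakdown NOL rose by 0.68 (SE 0.11) and NYC1 fell by 1.01 (SE 0.25). RCA, Rubisco activase, went from 2010 ± 63.1 to 6160 ± 1020 CPM and was the 1 of 3 carbon fixation genes that changed. None of 3 photosystem genes passed (0 of 3), including CAB1R, a light-harvesting protein at 12100 ± 2250 and 14500 ± 1720 CPM (log2 0.26, SE 0.26, adjusted p = 0.45). The chlorophyll, carbon fixation and photosystem lists had camera adjusted p between 0.65 and 0.98, and their counts other than that of chlorophyll synthesis were the same adjusted over the list alone.

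The brassinosteroid, jasmonate and gibberellin lists did not pass camera in wild type. CYP85A1 of brassinosteroid synthesis rose by 1.20 (SE 0.18), and CYP90B2, D2 and TUD1 fell by 1.92, 0.75 and 0.38, which left 1 up and 3 down of 7 (camera adjusted p = 0.73). Of 8 jasmonate genes, JAZ11 and JAZ12, repressors of the pathway, rose by 1.61 (SE 0.31) and 1.63 (SE 0.36) and AOS1 fell by 0.99 (SE 0.30; camera adjusted p = 0.74). GID1, the gibberellin receptor, rose by 0.64 (SE 0.10) and was the 1 of 3 gibberellin genes called (camera adjusted p = 0.73). Adjusted over the list alone, the counts of these lists were 1 and 3, 2 and 1, and 1 and 0. Over the 6 gibberellin genes as fixed, 1 rose and 2 fell (camera adjusted p = 0.73). Among markers of other tissues, 0 of 4 tested cell division genes (PCNA -0.24, SE 0.11, adjusted p = 0.081; camera adjusted p = 0.78) and 0 of 3 secondary-wall cellulose synthases (CESA7 0.21, SE 0.39, adjusted p = 0.7; camera adjusted p = 0.98) passed. Of 5 shoot apex genes, 0 had more than 4 counts summed over any group. LSI1, a silicon transporter and the 1 root marker tested, had -0.89 (SE 0.38, adjusted p = 0.079). Both tested inflorescence markers fell: MADS14, a gene of the floral transition, from 174 counts in control to 3 in drought (ratio 64.5, 95% counting interval 21.7 to 316), and MADS1 from 30 to 2 (ratio 16.7, 4.23 to 144).

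Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 10032 of 22833 tested genes between drought and control in wild type, 5116 up and 4916 down, of which 4135 changed at least 2-fold. With library size alone more fell than rose (4029 up and 4901 down), as in the fit of the 2 groups alone (5529 and 5650). Among loci without a name, LOC_Os11g43790 was at least 2050-fold higher under drought (0 counts in control), and LOC_Os09g19510 and LOC_Os09g19500 were at least 426-fold and 378-fold lower (0 counts in drought). Calls for ABA8OX2, AOS1, DREB2B, GluTR, MADS1, MAS, WRKY62 and WRKY76 were each lost under at least 1 alternative setting.

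The second comparison asks the same of idr1-1. Here too the LEA proteins rose, 7 of 8 with 0 down (8 and 0 adjusted over the list alone), and RAB21 went from 2 counts to 377 ± 202 CPM (ratio 11200, 95% counting interval 3110 to 92900). EMP1, 1 of these 8, rests on drought replicate 3 alone. It was at 0, 0 and 2.02 CPM in drought replicates 1, 2 and 3, and its log2 fold change of 6.92 was 0 without replicate 3. RAB16C rose by 3.98 (SE 0.24). In this group the level of RAB21 was 233, 290 and 608 CPM in replicates 1, 2 and 3, the last being the library that stood apart, where the LEA list had a median log2 level 0.51 above replicates 1 and 2. All but 1 of the 9 phosphatases 2C rose (8 up, 0 down, the same adjusted over the list alone), with PP2C49 at 5.64 (SE 0.41) and PP2C68 at 3.84 (SE 0.29). NCED3 rose by 2.74 (SE 0.30) and was the 1 of 5 abscisic acid metabolism genes called (camera adjusted p = 0.3), a list whose median lay 0.82 lower in replicate 3 than in the other two. Camera gave adjusted p = 9.9e-21 for the LEA proteins and 1e-09 for the phosphatases, and the phosphatases had adjusted p = 0.062 with an estimated correlation.

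The 3 secondary-wall cellulose synthases of the list rose together in idr1-1 under drought. CESA4 (LOC_Os01g54620) went from 2.84 ± 2.06 to 16.8 ± 4.15 CPM (log2 2.58, SE 0.40, adjusted p = 0.00042), CESA7 (LOC_Os10g32980) rose by 3.14 (SE 0.45, adjusted p = 0.00026) and CESA9 (LOC_Os09g25490) by 3.15 (SE 0.40, adjusted p = 0.00011). The list's counts were 3 up and 0 down both ways of adjusting (camera adjusted p = 0.0019, and adjusted p = 0.22 with an estimated correlation). The size of the rise rests on idr1-1 control replicate 2, where CESA4 was at 5.20 CPM against 1.92 and 1.40 in replicates 1 and 3: without it the rises were 3.33, 4.17 and 3.96 (list camera adjusted p = 4.5e-09). These enzymes build the cellulose of thickened walls, and the list was fixed as a marker of vascular and fibre tissue. Of 4 cell division genes, MCM2 rose (0.75, SE 0.22) and PCNA fell (-0.33, SE 0.11), each a call lost under some settings.

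Aquaporins and heat shock genes rose in idr1-1 as groups. Of 13 aquaporins 10 rose and 2 fell, both ways of adjusting (camera adjusted p = 2.3e-05, and adjusted p = 0.22 with an estimated correlation), with PIP2-6 at 2.79 (SE 0.18) and PIP1-2 at 1.49 (SE 0.11); the list's median was 0.75 lower in replicate 3 than in replicates 1 and 2. Of 9 heat shock genes 6 rose and 1 fell, both ways of adjusting (camera adjusted p = 4.1e-06, and adjusted p = 0.013 with an estimated correlation), with HSP101 at 2.42 (SE 0.12) and HSP17.7 at 3.96 (SE 0.29). Of 4 solute genes 2 rose and 2 fell (camera adjusted p = 0.11), with P5CS1 at 2.90 (SE 0.14) and TPP1 at -1.76 (SE 0.45). Over the 6 as fixed, 2 rose and 3 fell (camera adjusted p = 0.96). BZIP23 rose by 2.34 (SE 0.13), and 3 of 9 stress transcription factors rose and 1 fell (camera adjusted p = 0.2). Over all 16 as fixed, 8 rose and 2 fell (camera adjusted p = 0.00094, and adjusted p = 0.25 with an estimated correlation).

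Phytoalexin genes fell in idr1-1: 6 of 8 did, and 7 adjusted over the list alone (camera adjusted p = 0.0011, and adjusted p = 0.052 with an estimated correlation). CYP99A2 had -6.09 (SE 0.63), CPS4 -4.03 (SE 0.51) and KSL4 -4.10 (SE 0.76). Without idr1-1 drought replicate 1 CYP99A2 and KSL4 had -7.04 and -5.91, and without idr1-1 control replicate 2 CYP99A2 had -5.42. Of 8 clock genes 3 fell and 1 rose (4 and 1 adjusted over the list alone; camera adjusted p = 0.047, and adjusted p = 0.65 with an estimated correlation), with PCL1 at -4.54 (SE 0.44) and LHY at 1.57 (SE 0.24). All 8 were lower in replicate 3 than in replicates 1 and 2 (median -0.41), and the list's call was lost without it (adjusted p = 0.066), without idr1-1 control replicate 2 or 3 (0.068 and 0.058) and with the replicate number as a block (0.076). In the defence list PBZ1 (-0.87, SE 0.19) and NH1 (-0.74, SE 0.21) fell (2 of 4 down, 0 up; camera adjusted p = 0.23), and its median lay 1.13 higher in replicate 3 than in replicates 1 and 2. Of 14 genes of reactive oxygen removal 6 rose and 3 fell (camera adjusted p = 0.39), with SODCP at 1.10 (SE 0.13) and APX7 at -0.94 (SE 0.12). RBOHB had -0.43 (SE 0.13). RCA rose by 1.41 (SE 0.22), and 0 of 3 photosystem genes passed. Chlorophyll synthesis had 1 up and 1 down of 9, its breakdown 1 and 1 of 4, jasmonate 3 and 0 of 8, brassinosteroid 2 and 0 of 7, and gibberellin 1 and 0 of 3, each with a camera adjusted p of 0.22 or more. Adjusted over the list alone, every list of this comparison not given a second count here had the same counts. The jasmonate median was 0.70 higher and the chlorophyll synthesis median 0.86 lower in replicate 3. MADS14 had a log2 fold change of -4.95 (SE 0.64), and of -5.58 (SE 0.8) without replicate 3 of drought-stressed idr1-1.

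Over all genes the same test called 8129 in idr1-1, 4118 up and 4011 down, with 3659 changed at least 2-fold. More fell than rose with library size alone (3346 up and 3813 down), limma-voom (3762 and 4022), sample weights (4308 and 4321) and without replicate 3 of drought-stressed idr1-1 (4275 and 4315). LOC_Os08g34390 was at least 811-fold higher under drought (0 counts in control), and LOC_Os01g09190 fell from 1461 counts to 3 (ratio 525, 95% counting interval 179 to 2550). Calls for BRI1, CHLG, DREB1C, JAZ10, MCM2, NH1, P5CS2, PCNA, RBOHB, TPP1 and TPP2 were each lost under at least 1 alternative setting.

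**Figure D2:**
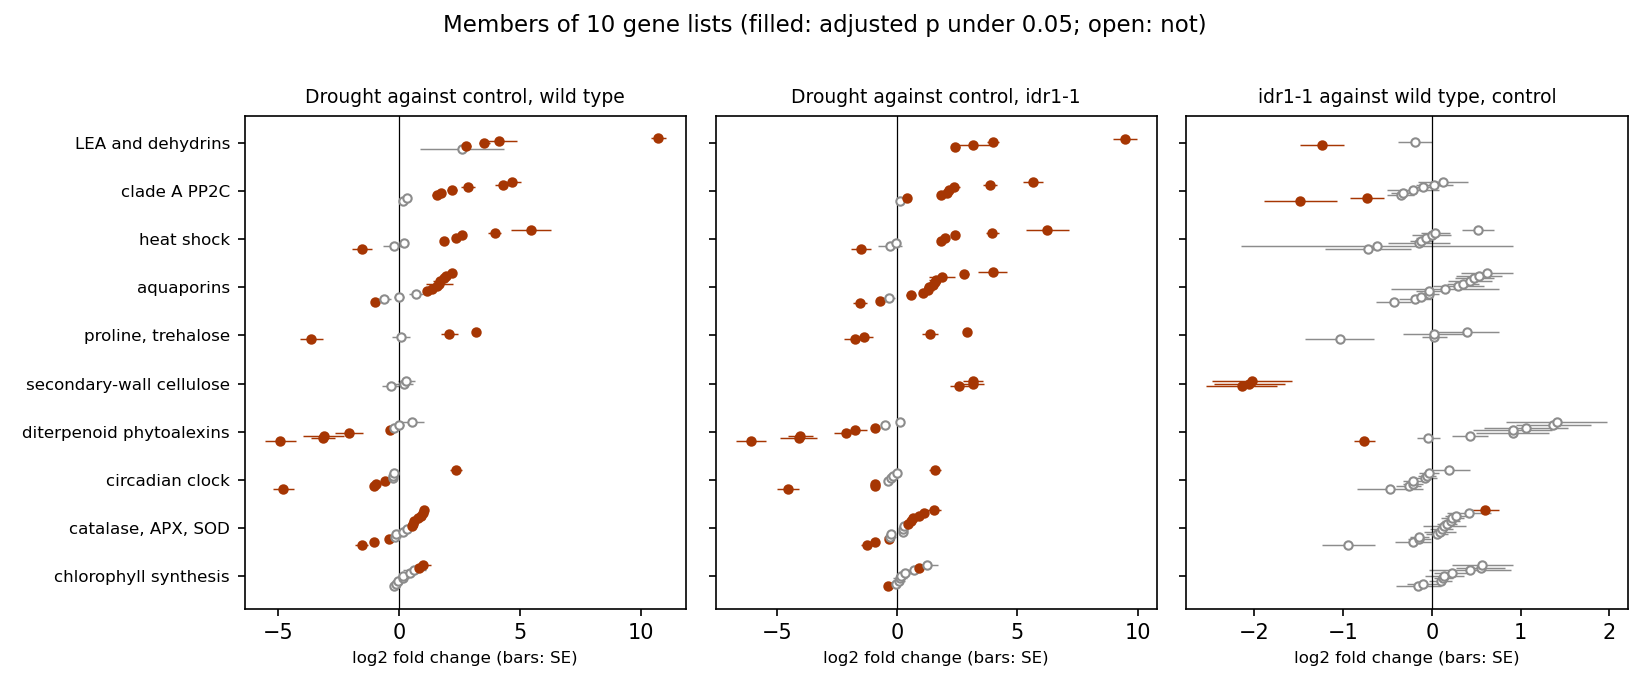
Log2 fold changes of the members of 10 gene lists in 3 comparisons, on linear axes whose range differs between panels; points are genes, bars are standard errors, and filled points have an adjusted p under 0.05. The 21 values resting on 3 counts or fewer in a group are not drawn; secondary-wall cellulose synthases lie to the right of 0 in drought-stressed idr1-1 and to the left of 0 in idr1-1 control leaves against wild type.

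The responses of both genotypes overlapped. Of the genes called, 6103 were called in both, 3034 up in both, 3040 down in both and 29 in opposite directions, and 75.1% of the idr1-1 calls were also wild type calls. Independent lists of these sizes would share 923 up and 864 down. The log2 responses correlated across the 22833 tested genes (Pearson r 0.83, Spearman rho 0.74), genes not being independent replicates, and their SDs were 1.24 in wild type and 1.16 in idr1-1. The comparisons share no libraries.

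The third comparison asks how idr1-1 differed from wild type without stress. The 3 secondary-wall cellulose synthases were lower in the mutant: CESA4 was at 2.84 ± 2.06 CPM against 12.5 ± 2.54 in wild type (log2 -2.14, SE 0.40, adjusted p = 0.013), and CESA7 and CESA9 had -2.03 (SE 0.45, adjusted p = 0.021) and -2.06 (SE 0.40, adjusted p = 0.015). The list had 3 down and 0 up both ways of adjusting (camera adjusted p = 6.2e-05, and adjusted p = 0.5 with an estimated correlation). Without idr1-1 control replicate 2, the highest of its group for all 3 genes, the values were -2.90, -3.06 and -2.86 (list camera adjusted p = 1.1e-14). Among LEA proteins and phosphatases 2C a few members were lower: the dehydrin RAB16C (-1.24, SE 0.25, adjusted p = 0.017), 1 of 8 LEA genes (camera adjusted p = 0.57), and the phosphatases PP2C06 (-0.73, SE 0.19, adjusted p = 0.039) and PP2C49 (-1.48, SE 0.41, adjusted p = 0.043), 2 of 9 (camera adjusted p = 0.41), with the same counts adjusted over the list alone. CPS2, a diterpene synthase of phytoalexin formation, was at 85.5 ± 9.70 CPM against 145 ± 15.9 (log2 -0.76, SE 0.12, adjusted p = 0.0084), the 1 of 8 phytoalexin genes called; adjusted over the list alone CYP99A2 was also higher (1.37, SE 0.42; 0.70, SE 0.34 without idr1-1 control replicate 2, at 12 CPM against 3.70 and 4.95), and the list had camera adjusted p = 0.57. The cytosolic ascorbate peroxidase APX1 was higher (0.60, SE 0.16, adjusted p = 0.038), 1 of 14 reactive oxygen genes both ways of adjusting.

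The other lists had 0 members past the threshold over all genes. Adjusted over the list alone, SD1 of gibberellin synthesis was higher (1.20, SE 0.37) and the receptor GID1 lower (-0.28, SE 0.10), and in the brassinosteroid list BZR1 was higher (0.57, SE 0.19) and CYP85A1 lower (-0.62, SE 0.19). Values of abundant members that did not pass include CAB1R (0.26, SE 0.26), RBCS-C of Rubisco (-0.25, SE 0.33), PIP2-7 (-0.03, SE 0.15), GI of the clock (-0.26, SE 0.14), HSP18.0 (0.52, SE 0.18), PBZ1 (0.22, SE 0.19), RBOHB (-0.44, SE 0.13, adjusted p = 0.056) and PCNA (0.17, SE 0.11).

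Over all genes 2391 were called between genotypes in control leaves, 1266 higher and 1125 lower in idr1-1, and 660 of them differed at least 2-fold. LOC_Os01g36294 (4.18, SE 0.98) and LOC_Os05g33160 (3.96, SE 0.50) were higher, and LOC_Os05g25610 and LOC_Os01g57250 were at least 453-fold and 368-fold lower (0 counts in idr1-1 control). The count fell to 292 (109 higher and 183 lower) and 512 without wild type control replicate 1 or 3, to 643 (403 and 240) and 207 without idr1-1 control replicate 1 or 3, to 1437 (41.7% higher in idr1-1, against 52.9%) with library size alone, and rose to 3822 with only the control groups in the fit and to 4557 in a fit without replicate 3 of drought-stressed idr1-1. The calls for all 3 cellulose synthases were lost without wild type control replicate 1 or without idr1-1 control replicate 1 or 3, those for CESA7 and CESA9 also without wild type control replicate 3 (adjusted p from 0.05 to 0.079), and the calls for RAB16C, PP2C06, PP2C49 and APX1 were lost in 4, 7, 8 and 7 of 17 alternatives, while those for CPS2 and RGA1 in control were lost in 0. Of the loci without a name, LOC_Os01g36294, LOC_Os01g57250, LOC_Os05g25610 and LOC_Os05g33160 lost their call in 8, 7, 1 and 0 of 17.

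**Figure D3:**
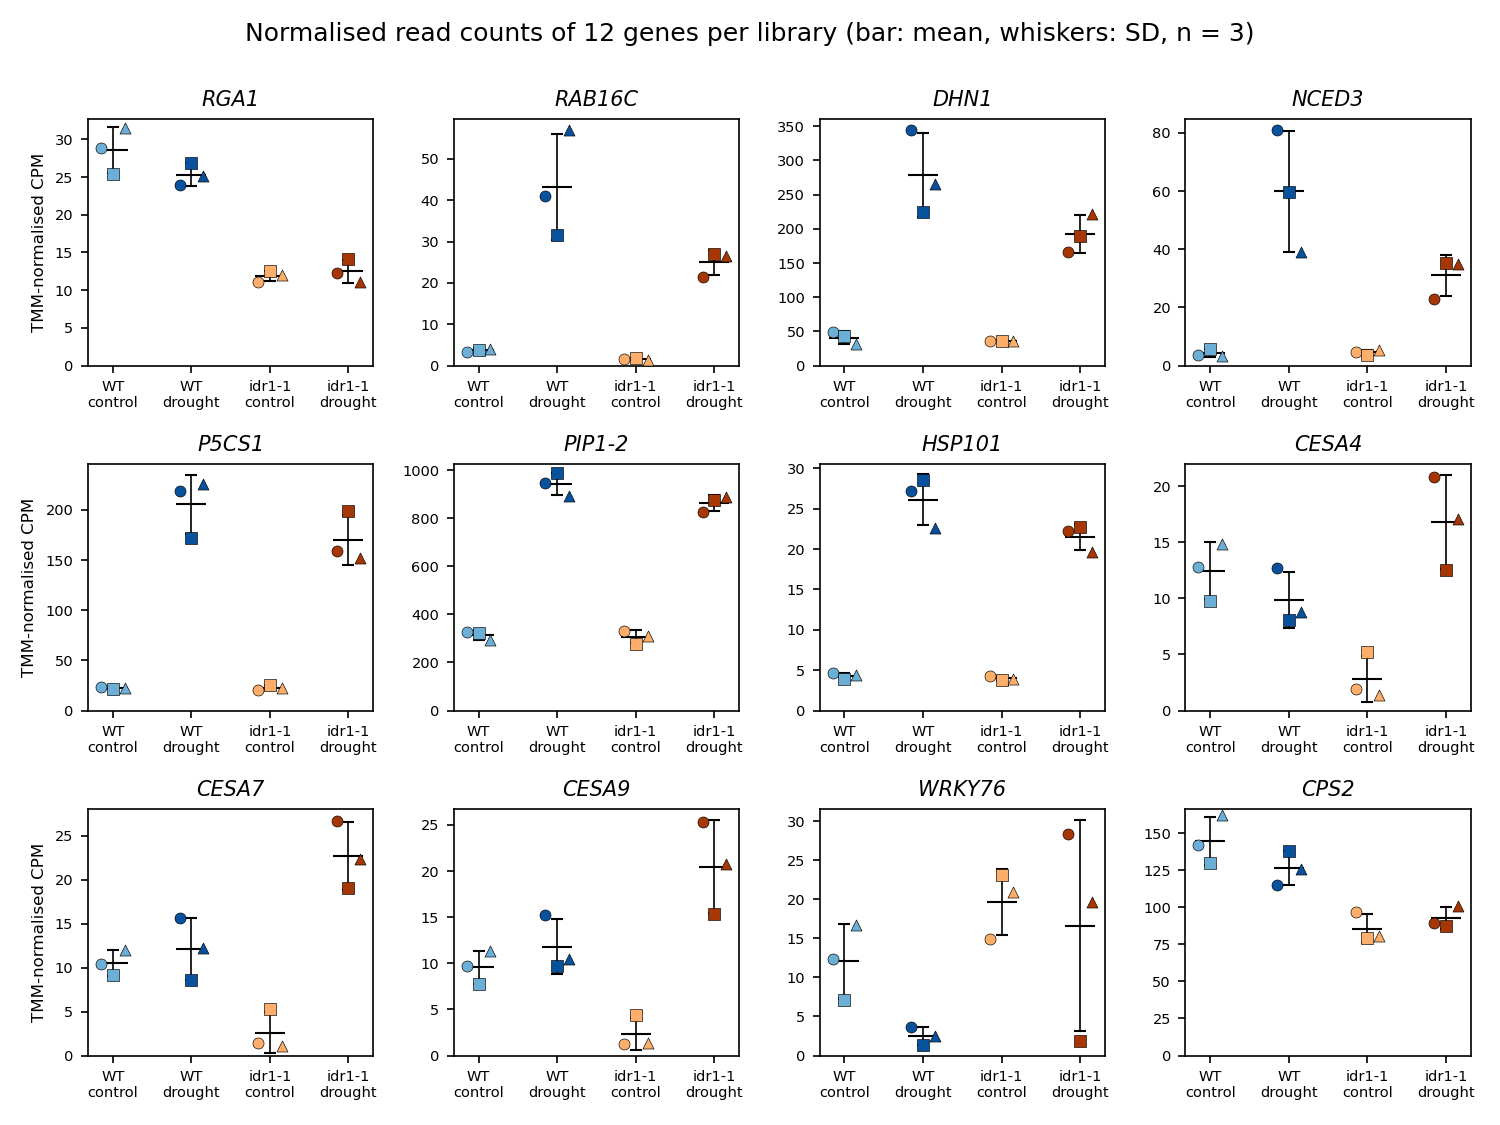
TMM-normalised CPM of 12 genes in each library, on linear axes that start at 0; symbols are replicates 1 (circle), 2 (square) and 3 (triangle), bars are means and whiskers SDs (n = 3). RGA1 lies at 11.1 to 14.1 CPM in the idr1-1 libraries and at 23.9 CPM or above in wild type, and CESA4, CESA7 and CESA9 are lowest in idr1-1 control leaves.

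The fourth comparison asks how the genotypes differed under drought. LEA proteins stood lower in idr1-1 as a list (median log2 fold change -1.11, camera adjusted p = 2.3e-09, and adjusted p = 0.16 with an estimated correlation), with 0 of 8 members past the threshold over all genes and 7 down adjusted over the list alone. RAB21 was at 377 ± 202 CPM against 884 ± 142 in wild type (-1.23, SE 0.30, adjusted p = 0.12), LEA3-1 at 74.8 ± 24.4 against 192 ± 46.5 (-1.36, SE 0.26, adjusted p = 0.064) and RAB16B at 118 ± 27.4 against 234 ± 31.1 (-0.99, SE 0.17, adjusted p = 0.052). The phosphatases 2C had a median of -0.29 (camera adjusted p = 0.02, and adjusted p = 0.59 with an estimated correlation) and 0 of 9 members past the threshold either way. NCED3 had -0.95 (SE 0.26, adjusted p = 0.16) and passed adjusted over the list alone.

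No other list passed, and RGA1 was the 1 list member called over all genes. The defence list had a median of 1.53 (camera adjusted p = 0.089), and in it WRKY62 (3.79, SE 0.96, adjusted p = 0.13) and WRKY76 (2.74, SE 0.72, adjusted p = 0.14) passed adjusted over the list alone, though their levels in idr1-1 ranged from 0.194 to 8.69 and from 1.90 to 28.4 CPM between replicates (WRKY62 2.99 without idr1-1 drought replicate 3, WRKY76 2.11 without replicate 1). Of the phytoalexin genes CPS2 (-0.45), KSL7 (-1.40) and CYP71Z7 (-0.57) passed adjusted over the list alone (camera adjusted p = 0.14). So did TUD1 (0.24, SE 0.07) and CYP85A1 (-0.62, SE 0.18) of the brassinosteroid list, SLR1 (0.27, SE 0.10) and GID1 (-0.28, SE 0.10) of the gibberellin list, and HSP26.7 (3.58, SE 1.00, at 9.10 ± 11.7 CPM in idr1-1; 1.65, SE 0.75 without its replicate 3) and HSFA2C (-0.37, SE 0.11) of the heat shock list. The lists not named for this comparison had 0 members past the threshold that way. The cellulose synthases had a median of 0.79 (camera adjusted p = 0.061), and CESA7 was at 22.7 ± 3.87 CPM against 12.1 ± 3.50 (0.90, SE 0.39, adjusted p = 0.34). With the lists as fixed, the photosystem, stress transcription factor and cellulose synthase lists also passed camera (adjusted p = 1e-04, 0.00028 and 0.038), with adjusted p = 0.64, 0.41 and 0.56 with an estimated correlation and 0, 1 and 0 members called over all genes.

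Over all genes 42 were called between genotypes under drought, 10 higher and 32 lower in idr1-1, with 24 at least 2-fold apart and 3113 at an unadjusted p under 0.05. LOC_Os11g01240 (1.56, SE 0.21) and LOC_Os10g04270 (1.10, SE 0.12) were higher, and LOC_Os08g02904 and LOC_Os10g04130 were at least 965-fold and 368-fold lower (0 counts in idr1-1 drought). The calls for LOC_Os11g01240 and LOC_Os10g04270 were lost in 4 and 2 of 16 alternatives, and those for the other 2 loci in 0. Without replicate 3 of drought-stressed idr1-1 the count was 1074 (509 higher and 565 lower), with 5 of 8 LEA genes down (RAB21 -1.77, SE 0.16, adjusted p = 0.00056; list median -1.54) and the phosphatase list no longer past the threshold (adjusted p = 0.069, and 0.099 and 0.18 without idr1-1 drought replicate 1 or wild type drought replicate 3). The count was 506 without replicate 2, where the balance turned (397 higher and 109 lower), and 9 without replicate 1 of that group, 13, 18 and 16 without wild type drought replicate 1, 2 or 3, and 18 (11.1% higher in idr1-1, against 23.8%) with library size alone. It was 555 with DESeq2 (284 higher and 271 lower) and 3 with only the drought groups in the fit.

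The last comparison tests whether the drought response differed between genotypes. The secondary-wall cellulose synthases were the 1 list past the threshold: their response was larger in idr1-1 by a median of 2.92 on the log2 scale (camera adjusted p = 3.2e-09, and adjusted p = 0.11 with an estimated correlation). Over all genes 0 of the 3 passed, with CESA4 at 2.92 (SE 0.53, adjusted p = 0.069), CESA7 at 2.93 (SE 0.59, adjusted p = 0.081) and CESA9 at 2.85 (SE 0.53, adjusted p = 0.07), and all 3 passed adjusted over the list alone. Without replicate 3 of drought-stressed idr1-1 all 3 passed over all genes (adjusted p = 0.03, 0.037 and 0.031), as they did without idr1-1 control replicate 2, with larger values (3.67, 3.96 and 3.66; list camera adjusted p = 2.6e-26). Most of this difference lay in control leaves, where the list median between genotypes was -2.06, against 0.79 under drought. It uses the same idr1-1 control libraries as the control comparison and is not a separate result from the lower level there. The LEA list had camera adjusted p = 0.67 and the phosphatases adjusted p = 1, with RAB21 at -2.14 (SE 2.44, adjusted p = 0.74). The RAB21 value rests on 1 control count in wild type and 2 in idr1-1. LEA3-1 had 2 counts in wild type control and RAB16B 2 in idr1-1 control. For LEA genes with so few control counts the test does not show that the responses were alike. Adjusted over the list alone, TPP1 (1.85, SE 0.66) and TPP2 (-1.49, SE 0.53), WRKY62 (3.59, SE 1.21; 2.80 without replicate 3 of drought-stressed idr1-1) and KSL7 (-2.31, SE 0.67) also passed, and RGA1 had 0.25 (SE 0.16, adjusted p = 0.48).

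Over all genes 11 passed, and 3540 had an unadjusted p under 0.05. The difference (idr1-1 response less that of wild type) was positive in 3 of the 11 and negative in 8. In 5 of the 11 the idr1-1 response was larger than that of wild type, in 6 it was opposite, and in 0 it was smaller. LOC_Os04g58910 (1.04, SE 0.14) and LOC_Os05g32500 (1.11, SE 0.15) had the higher values, and LOC_Os09g28650 (-1.17, SE 0.12) and LOC_Os10g39100 (-2.0, SE 0.23) the lower ones. Leaving out 1 library gave 0 (wild type control replicate 1 or 3, idr1-1 control replicate 1, wild type drought replicate 2, idr1-1 drought replicate 1), 2 (idr1-1 control replicate 3, wild type drought replicate 3), 7 (wild type drought replicate 1), 14 (wild type control replicate 2), 241 (idr1-1 control replicate 2), 582 (idr1-1 drought replicate 2) or 489 (idr1-1 drought replicate 3), and DESeq2 called 708. The balance turned to more positive than negative differences without idr1-1 control replicate 2 (157 and 84), without idr1-1 drought replicate 2 (490 and 92), with DESeq2 (437 and 271), with sample weights (204 and 167) and with no filter on low counts (58 and 24).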

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

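The tests of the RGA1 level, depth and stage of response in the library that stood apart, the counts of lone genes and of genes with whole counts in the pattern of near-absent genes, and the control counts at matched group sizes were chosen after the results were seen.

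In the test of the difference of responses 11 genes passed in the main fit. The count was 0 with the replicate number as a block and 0 to 582 with 1 library left out. The secondary-wall cellulose synthases passed as a list at the preset correlation (camera adjusted p = 3.2e-09) and not with an estimated one (adjusted p = 0.11). The list's adjusted p ranged from 2.6e-26 to 0.11 over alternatives, and 0 of its 3 genes passed over all genes. The loci with the lowest p values gave log2 differences of 1.04 (LOC_Os04g58910), 1.11 (LOC_Os05g32500), -1.17 (LOC_Os09g28650) and -2.0 (LOC_Os10g39100), and their calls were lost in 10, 11, 7 and 8 of 21 alternatives. Of 100 splits of the libraries drawn from 200, each keeping the treatment and exchanging genotypes, 4 gave at least 11 genes, the real one included, and the highest other gave 3303. These splits do not settle whether chance can be excluded. All 4 were among the 8 drawn splits that left the control groups as they are and so keep the genotype difference of control leaves (2391 genes). The highest other was one of them, with 2 drought libraries of each genotype exchanged. The other 92 exchanged control libraries, which puts that difference into the spread within groups, and 0 of them reached 11.

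Replicate 3 of drought-stressed idr1-1 differed from replicates 1 and 2 by at least 1 on the log2 scale in 2660 genes, 1731 higher and 929 lower. Several explanations are argued against by the tables: a wild type plant under the label (RGA1 at 11.1 CPM, lowest wild type value 23.9), depth (a total of 20.1 M counts, within the range of the other libraries) and a few abundant genes (chi-square per gene of 57.7 without the 100 most abundant, against 14.3 in the highest other pair). A stronger form of the wild type drought response as the main source is argued against too, since that response explained 1.4% of the variance of the difference. This value covers only changes in proportion to the wild type response, so a later stage that involves other genes stays open. On the first component the library lay at 76.6, against 52.9 and 66.4 for replicates 1 and 2 and 80 to 86.8 for wild type drought. The hour of harvest stays open. All 8 clock genes were lower in that library (-1.42 to -0.28), both LHY, which rose in the 2 drought responses, and PCL1, which fell. Their median absolute difference was 0.41 (95th percentile of matched random lists 0.71) and their median -0.41 (percentile 28.4). Values within the spread of random lists neither point to another hour nor exclude one. Dividing leaf-base tissue in the sample stays open too: the 4 tested cell division genes went both ways (-0.46 to 0.38, median -0.04, upper bound of matched random lists 0.78), and CYCB2-1 and MCM4, too low to test, were at 0.945 and 0.348 CPM against at most 0.436 and 0 in replicates 1 and 2. In that library the defence and jasmonate lists were higher by medians of 1.13 and 0.70 (percentile 100 of matched random lists for both), while abscisic acid metabolism was lower by 0.82 (percentile 0.2). The reference is the mean of replicates 1 and 2, and some members were low in replicate 2 instead. WRKY76 was at 28.4, 1.90 and 19.6 CPM in replicates 1, 2 and 3, and JAZ10 at 15.9, 10.4 and 16.8. Others were alike in replicates 1 and 2 and higher in replicate 3, such as PBZ1 (135, 134 and 211) and JAZ11 (13.4, 13 and 28.5). A wound or pathogen in the plant of replicate 3, or a difference in handling, stays open and was not tested, and no biological explanation is given by the design.

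In idr1-1, 8 genes had at most 1 count in every library while wild type had at least 3 in every library; the mirror pattern held for 1 gene. LOC_Os08g02904 (7244 counts over the wild type libraries, 1 over idr1-1) and LOC_Os10g04130 (2180 and 0) were the most abundant of them. Low detection in wild type is argued against for the pattern as a whole by a median summed count of 204.5 (bound 60). It stays open for LOC_Os12g05290 and LOC_Os12g15780, with 40 and 25 counts over the wild type libraries and 3 and 2 over idr1-1. Reads shared with near-identical copies are argued against for 3 of the 6 genes above 60 counts, LOC_Os06g20960, LOC_Os08g02900 and LOC_Os10g04130, whose counts were whole in every wild type library, and stay open for the others: over all 8 genes 25% of the wild type counts were not whole, within the spread of matched draws (median 12.5%, 95th percentile 31.2%), and such a share excludes nothing. Loss of neighbouring loci together may account for LOC_Os08g02900 and LOC_Os08g02904, the 1 pair within 20 loci (95th percentile of matched draws 0). The other 6 of the 8 genes had no such neighbour. The count takes in only loci with at least 3 counts in every wild type library, so a loss of silent neighbours would not be seen. Whether expressed loci beside these 6 genes were intact was not tested, and for them this explanation stays open. A difference in the genetic background of the lines, or an effect of the mutation on these genes, stays open and was not tested.

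Genotype calls were fewer under drought (42) than in control (2391). The spread added by replicate 3 of drought-stressed idr1-1 may account for part of this, since the drought count without it was 1074, with 2 idr1-1 libraries against 3 of wild type. In fits without it that also left out idr1-1 control replicate 1, 2 or 3, so that both comparisons had these group sizes, the control count was 2849, 3881 or 1933. The noise-corrected variance of the genotype difference across genes was computed from replicates 1 and 2 of each group alone, without replicate 3 of any group. It was 0.153 under drought and 0.186 in control, a ratio of 0.82 (0.745 to 0.896 over 1000 resamples of genes). The interval lies below 1 but spans the bound of 0.8 set for a smaller difference, and resampling genes leaves out the spread between libraries, so this explanation stays open. Splits of 6 libraries into 3 and 3 number 10 and are too few for a share under 0.05. In control 1 split (the real one, 2391 genes) reached the count, with 0 in the highest other, and under drought 2 did, with 43 in the highest other against 42. For drought against control, 1 split (the real one) reached 10032 in wild type and 1 reached 8129 in idr1-1, with 0 in the highest other in both. Every other split mixes the 2 groups compared. A real difference between them then enters the spread within groups, so a count of 0 in such splits excludes nothing.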

How the results depend on the processing

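The fits with sample weights, a robust fit, all fixed list members or no replicate 3 of drought-stressed idr1-1 in every comparison were chosen after seeing the data; the causes of the changes below were not tested except where named. Both drought responses stayed within 1.5 times of 10032 and 8129 genes in every alternative (8185 to 8758 and 6480 to 8590 when 1 library was left out), and DESeq2's size factors, a filter of 1 CPM and the robust fit moved no count of genes by more. Of 141 called results for named genes and loci, 105 kept their call in every alternative, 36 lost it in at least 1, and 0 changed sign. With library size alone the counts were 1437 in control, 18 in drought and 2 for the difference of responses (50% of them positive, against 27.3%). Without a filter they were 79 in drought and 82 for the difference, with 36489 genes tested. DESeq2 gave 555 and 708 and limma-voom 68 and 6 for these, sample weights 4657, 859 and 371 for all 3, fits of 2 groups 3822 in control and 3 in drought, and the fit without the library apart 4557 in control.

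Leaving out 1 library gave 207 to 1879 in control, 9 to 1074 in drought and 0 to 582 for the difference, where 3540 genes had an unadjusted p under 0.05 with all libraries in edgeR. Lists past the threshold numbered 4 to 6 (wild type response), 6 to 8 (idr1-1 response), 1 to 2 (control), 1 to 4 (drought) and 1 to 3 (difference) in those fits, 2, 2, 0, 0 and 0 with an estimated correlation, 13 and 12 for the responses with fry, which asks another question, 4 in drought with library size alone and 6 in drought with all fixed members: 5 of the 20 lists tested elsewhere and the G protein list (adjusted p = 0.038), which is tested there alone. The stress transcription factor list was gained in both responses and in drought. The correlation of responses was 0.52 (Pearson) and 0.49 (Spearman) without a filter, which adds genes of few counts, 0.85 and 0.76 with the filter of 1 CPM, and 0.77 to 0.82 and 0.69 to 0.75 with 1 library left out. With the replicate number as a block the counts were 1112 in control, 14 in drought and 0 for the difference; the numbers do not pair the samples, since 2 of 18 same-numbered pairs correlated above 0.1 (range -0.32 to 0.22) and 1 library correlated best with its own number. Depth limits genes of few counts, such as RGG1.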

Other observations

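The values here come from the fit without replicate 3 of drought-stressed idr1-1, which was chosen after seeing the data, as were the genes named. They compare drought-stressed idr1-1 with drought-stressed wild type. Of 13 aquaporins 3 were higher and 0 lower: TIP2-2 (0.63, SE 0.09, adjusted p = 0.0065), PIP2-2 (0.56, SE 0.14, adjusted p = 0.046) and TIP1-1 (0.38, SE 0.10, adjusted p = 0.048), though the list did not pass (camera adjusted p = 0.12). In the library left out these 3 lay below every wild type drought library (TIP2-2 at 120 CPM against 167 to 206, PIP2-2 at 177 against 291 to 345, TIP1-1 at 290 against 381 to 436), and the list was at a median of -0.75 against replicates 1 and 2. LSI1, the 1 root marker tested, was also called higher in this fit (0.84). In the library left out it was at 3.94 CPM, against 7.19 to 9.96 in wild type drought. The chlorophyll synthesis list (median 0.35, camera adjusted p = 0.006) and the photosystem list (median 0.46, camera adjusted p = 0.011) passed at the preset correlation and not with an estimated one (adjusted p = 0.38 for both), and each had 1 called member, DVR (0.59, SE 0.13) of 9 and PSAH (0.46, SE 0.11) of 3 tested. Carbon fixation did not pass (camera adjusted p = 0.12), while for the difference of responses chlorophyll synthesis and photosystem had camera adjusted p = 0.38 and 0.22. The library left out held chlorophyll synthesis and photosystem at medians of -0.86 and -0.68 against replicates 1 and 2. With all libraries these 2 lists had camera adjusted p = 0.48 and 0.15 (adjusted p = 0.81 and 0.6 with an estimated correlation), and 0 members called.

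In the same fit ABA8OX3, which breaks abscisic acid down, was higher in idr1-1 (0.76, SE 0.13, adjusted p = 0.01), as was ZEP of its synthesis (0.63, SE 0.12, adjusted p = 0.016), while P5CS2 of proline synthesis was lower (-1.30, SE 0.21, adjusted p = 0.01). CYP90B2 of brassinosteroid synthesis was higher (1.32, SE 0.25, adjusted p = 0.016) and CYP85A1 lower (-0.40, SE 0.10, adjusted p = 0.045). The drought response itself differed for TIP1-1 (0.82, SE 0.13, adjusted p = 0.02), P5CS2 (-1.32, SE 0.29, adjusted p = 0.046) and CYP90B2 (1.46, SE 0.33, adjusted p = 0.046). The library left out ran the other way for most of them. In it ABA8OX3 (20 CPM against 38.7 to 52.2), ZEP (411 against 746 to 928) and CYP90B2 (10.8 against 11.7 to 23.7) lay below every wild type drought library, P5CS2 (33.6 against 28.7 to 36.2) lay among them, and CYP85A1 (13.5 against 30.7 to 32.1) was lower as in replicates 1 and 2. None of these was called between genotypes with all libraries.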
